A study of Mus musculus with 10 samples.

How the data were processed

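The series measured messenger RNA in mouse LSK cells (lineage-negative, Sca1-positive, c-kit-positive) that had been transduced with retroviral HOXB4-ER or HOXB4const and selected by GFP. Per the labels' protocols, the cells were expanded for 14 days in serum-free medium with cytokines and 10 nM TMX, sorted, cultured for 12 h more with TMX, and divided into cultures with and without TMX. RNA (0.7 to 1 µg) was amplified linearly with T7 polymerase by a protocol for small samples and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels. All 10 arrays were used.

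The deposited values are on the log2 scale, with 1 signal for each probe set and array. The submitters' processing notes name GCOS and RMA without saying what each was used for. In the deposited values, the mean of 2 to the power of the value, without the lowest and highest 2%, was 100.0 on every array, the quantiles differed between arrays, and values reached below 0, which is how log2 of the GCOS (MAS 5) signal with global scaling behaves and how RMA does not. The values were therefore treated as log2 GCOS signals and were not normalized again. The background correction behind them and any detection calls are not given in the sources used here, nor are scan dates, hybridisation batches or the animals behind each replicate number.

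Of the 45101 probe sets, 64 controls were left out of the tests. Of the other 45037, 34945 have 1 gene symbol in the platform annotation, 932 have several and are named here by probe set only, and 9160 are not listed in it. Symbols were checked against a RefSeq gene table (assembly GRCm38.p6) and 0 needed an update. No coordinates are given.

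Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 5 groups over all 10 arrays, so that the groups share an estimate of the spread (5 residual and 2.21 prior degrees of freedom), empirical Bayes moderation without a trend, two-sided tests and Benjamini-Hochberg adjustment within each of the 6 comparisons. The threshold was an adjusted p under 0.05. A difference is without TMX minus with TMX, 4 h minus 1 h, or HOXB4-ER minus HOXB4const. Errors of differences are limma's moderated standard errors and errors of levels are SDs with n = 2, unless stated otherwise.

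There were 30 gene lists of 1050 entries (970 measured), written from general knowledge of the tissue, the pathways and possible contaminating cell types before the data were examined, together with the comparisons, tests and main alternatives. The Wnt, Notch, FGF and TNF lists were included with knowledge of the study's topic, so they are not fully independent of it. Each of the 18193 genes was represented by its probe set with the highest mean. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 30 lists of a comparison. With an estimated correlation, camera passed 0 lists in any comparison. Limma's fry, which asks whether the genes of a list move one way on balance, passed the unfolded protein list alone after 4 h and 0 lists elsewhere, and its test for change in either direction passed 2 lists after 4 h, 2 between 4 h and 1 h, and 1 between the constructs with TMX. List members were also adjusted over the list alone. That adjustment does not count the other lists, so with 30 lists some members can pass by chance in a comparison. The standard errors of members come from the fit over the 18193 genes, so that they differ slightly from those over all probe sets.

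The text names genes by a rule fixed with the design: in each comparison up to 12 higher and 12 lower genes past the threshold (6 and 6 for the last 3 comparisons) with no overlap of arrays, filled up to 10 with those of the smallest p and reported as not passing; Hoxb4 and Esr1 in every comparison; and, for each list, members past the threshold or, where the list alone passed, the 4 with the smallest p. Since no probe set passed, the rule gave 10 genes that did not pass for each comparison. Some of these are given by their number and direction only.

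Arrays of the same replicate number were alike across groups. What a replicate number stands for is not given in the sources used here, and the main fit did not include it. The differences between replicate 2 and replicate 1 correlated between groups in 10 of 10 pairs of groups (0.210 to 0.527, median 0.314, over 22519 brighter probe sets), and per the labels' protocols the populations were divided between treatments. The 3′ minus 5′ difference of the Gapdh control probe sets, a sign of RNA integrity or amplified length, was 1.10 ± 0.26 on replicate 1 and 2.72 ± 1.08 on replicate 2 arrays (SD, n = 5, exact two-sided permutation p = 0.00794, higher for replicate 2 in 5 of 5 groups). By group it was 1.39 ± 0.50 for HOXB4-ER with TMX, 1.24 ± 0.33 and 2.45 ± 1.45 after 1 h and 4 h without, and 1.83 ± 1.55 and 2.63 ± 1.91 for HOXB4const with and without TMX (SD, n = 2). Levels of lists on single arrays were compared between replicate numbers by exact permutation over 252 splits with adjustment over the 30 lists. These permutations treat the arrays as independent, which cultures divided from shared populations are not. Correlations between arrays lay between 0.784 and 0.895, and 0 of 45 pairs of arrays were identical.

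The alternatives were quantile normalization, centring arrays on their medians, the 22519 probe sets at or above the median mean level alone, empirical Bayes with a trend and robust fitting, the arrays of the compared groups alone, the replicate number as a block within or across constructs, a 1.5-fold minimum, gene means in place of probe sets, and leaving out each array. The Gapdh covariate, leaving out both arrays that stood apart, combined settings with a block, and the scaling alternatives for the lists were added after the data had been seen.

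The procedure was tested on simulated data for HOXB4-ER at 4 h, in 10 runs over 45037 probe sets with 200 planted changes each. It recovered 0% of changes of 1 or 2 on the log2 scale and 34.2% of changes of 4, with 7 false calls in all. With 22519 brighter probe sets, a trend and robust fitting, it recovered 1.04%, 27.2% and 69.8%, with 39 false calls. A list shifted by 0.5 among 18193 genes was found in 10 of 10 runs, with 0 calls of other lists. The simulated genes varied independently, whereas the estimated correlation between genes of a list reached 0.45 for TNF and NF-kB. These runs therefore do not show how often lists of correlated genes are called falsely.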

Results

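Gene expression was measured in mouse haematopoietic stem and progenitor cells that carried a retroviral HOXB4 transgene. HOXB4 is a homeobox transcription factor that expands blood stem cells in culture when overexpressed. In HOXB4-ER the protein is fused to a hormone-binding domain of the oestrogen receptor, so that 4-hydroxytamoxifen (TMX) keeps it active in the nucleus and removal of TMX switches it off. HOXB4const is the unmodified protein, which does not need TMX. The cells had been expanded for 14 days with 10 nM TMX, sorted as GFP-positive, lineage-negative, Sca1-positive and c-kit-positive cells, and then kept with or without TMX. The 10 Affymetrix arrays form 5 groups of 2: HOXB4-ER with TMX for 1 h, HOXB4-ER without TMX for 1 h, HOXB4-ER without TMX for 4 h, HOXB4const with TMX for 1 h and HOXB4const without TMX for 1 h. HOXB4-ER cells kept with TMX for 4 h and HOXB4const cells at 4 h were not analysed here.

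Each array gave a log2 signal for 45037 probe sets, with array medians between 3.96 and 5.32 on the log2 scale. The number of arrays limits the precision: for the 22519 probe sets at or above the median mean level, the median 95% confidence interval of a difference between groups reached 1.33 to either side. The median SD within groups lay between 1.32 and 1.43 for probe sets with a mean level below 3.47 and was 0.35 for those above 8.34. The HOXB4const without TMX replicate 1 array stood apart, with a median of 5.32 and 0.0155% of its values below 0. The HOXB4-ER without TMX 1 h replicate 1 array had the highest spike-in controls, at 12.7.

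The arrays with the same replicate number resembled each other in blood cell and proliferation genes, whatever the construct or treatment. The 3′ minus 5′ difference of the Gapdh control probe sets, a sign of RNA quality, split by the same numbers, at 1.10 ± 0.26 on replicate 1 and 2.72 ± 1.08 on replicate 2 arrays (SD, n = 5 each, exact two-sided permutation p = 0.00794), so cell state and RNA quality are not separated here. Monocyte and macrophage markers lay 1.12 ± 0.28 above the mean of all arrays on the replicate 1 arrays and at −1.15 ± 0.45 on the replicate 2 arrays (SD, n = 5 each, log2, exact two-sided permutation p = 0.00794, adjusted p = 0.0216). Dendritic and antigen presentation markers (0.78 ± 0.56 against −0.87 ± 0.33), immediate early genes (0.60 ± 0.20 against −0.51 ± 0.09) and genes of the TNF and NF-kB response (0.59 ± 0.44 against −0.54 ± 0.22) were also higher on every replicate 1 array. Stem cell regulators (−0.12 ± 0.10 against 0.18 ± 0.09), S-phase genes (−0.18 ± 0.14 against 0.21 ± 0.13), G2 and M-phase genes (−0.22 ± 0.09 against 0.21 ± 0.07) and MYC targets (−0.19 ± 0.09 against 0.16 ± 0.11) were lower on every replicate 1 array. Of the 30 gene lists, 13 passed this test, 8 higher in replicate 1 and 5 higher in replicate 2, and for 11 lists the arrays of the 2 numbers did not overlap. An exact p of 0.00794 is the smallest that 5 arrays against 5 can give, and this split was tested after the arrays had been seen to pair by number.

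**Figure D1:**
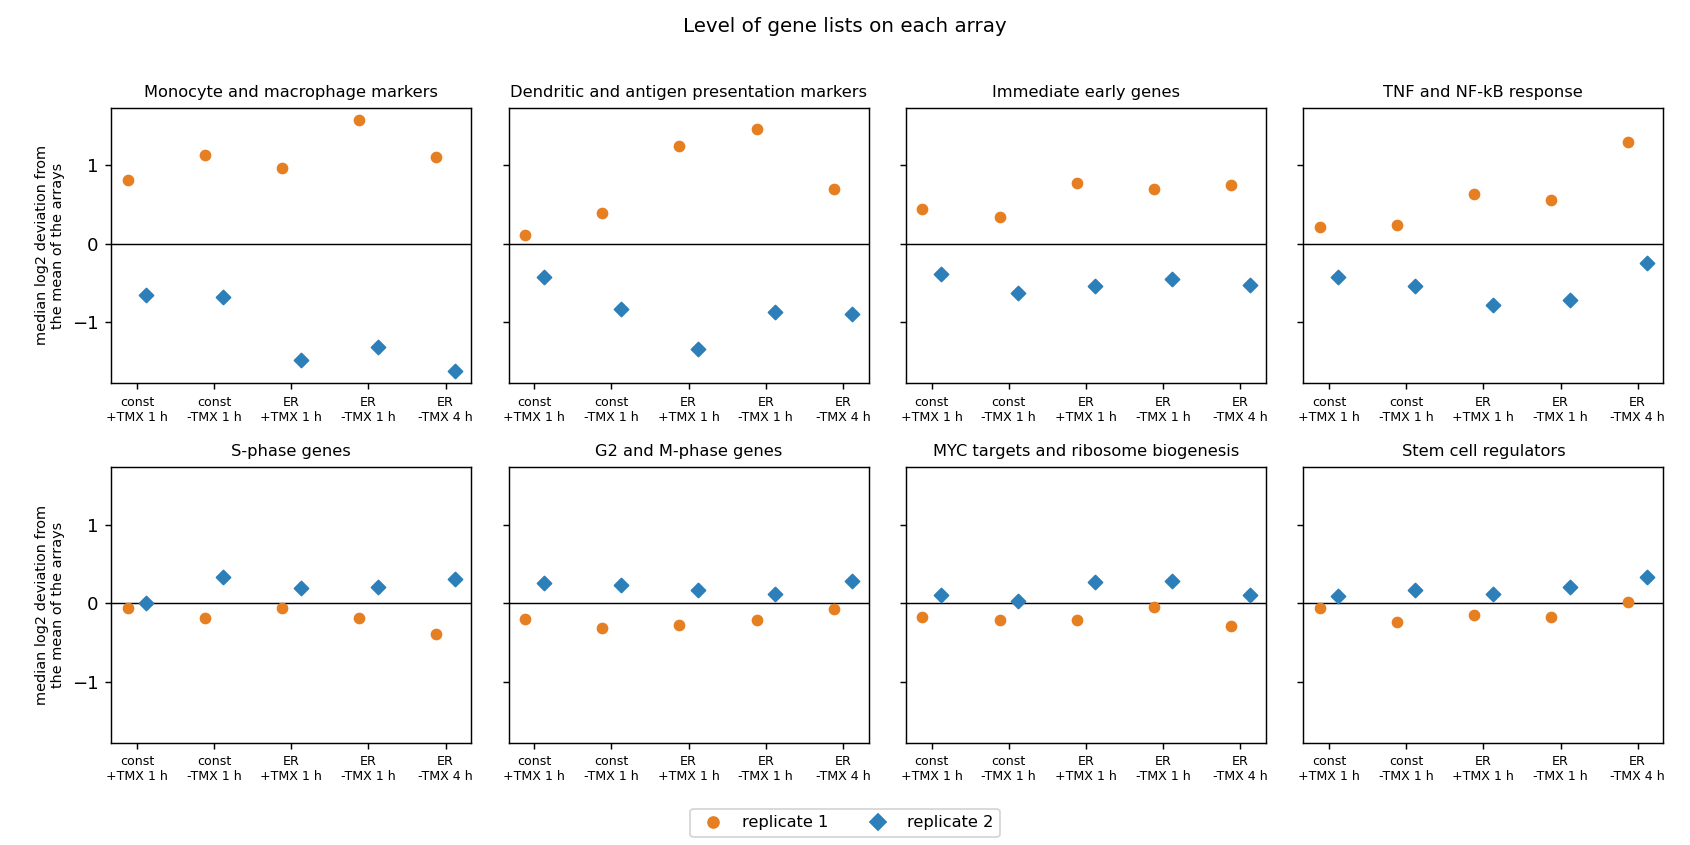
Median log2 deviation of 8 gene lists on each of the 10 arrays from the mean of the arrays, by group (ER, HOXB4-ER; const, HOXB4const), with circles for replicate 1 and diamonds for replicate 2. The replicate 1 arrays lie above all replicate 2 arrays in the upper 4 panels and below them in the lower 4.

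The transgene was examined first. The brighter of the 2 Hoxb4 probe sets read 5.23 ± 0.39 in HOXB4-ER cells with TMX, 5.95 ± 0.24 after 1 h and 4.99 ± 0.88 after 4 h without it (log2, SD, n = 2). In HOXB4const cells it read 6.04 ± 0.29 with TMX and 6.14 ± 0.63 without. The Hoxb4 differences on withdrawal were 0.72 ± 0.59 and −0.24 ± 0.59 in HOXB4-ER cells and 0.11 ± 0.59 in HOXB4const cells (standard error), and none passed limma's test. The brightest of the 3 probe sets of Esr1, the gene of oestrogen receptor alpha, gave −0.54 ± 0.63, 0.09 ± 0.63 and −0.40 ± 0.63 in the same order. For the difference between the constructs after 1 h, 4 h minus 1 h, and HOXB4-ER minus HOXB4const with TMX, Hoxb4 gave 0.61 ± 0.84, −0.96 ± 0.59 and −0.81 ± 0.59, and Esr1 −0.15 ± 0.90, 0.63 ± 0.63 and −0.25 ± 0.63. The dimmer probe sets of both genes did not pass in any comparison either. TMX acts on the location of the fusion protein, so these transcript levels do not check the withdrawal, and where the probes lie relative to the transgene is not given in the sources used here.

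The first question was which genes respond within 1 h when HOXB4 is switched off. None of the 30 lists shifted as a group after 1 h: median differences ran from −0.12 for stem cell regulators to 0.32 for lymphoid markers. FGF and ERK signalling genes had a median of 0.22 (camera's direction was down), TNF and NF-kB response genes 0.00, p53 targets −0.06 and erythroid markers 0.19. Among the members of the fixed lists, 2 passed when adjusted over the list alone. Over all probe sets neither passed (limma adjusted p = 0.496 for Hoxb5 and 0.536 for Zbtb46). With 30 lists adjusted separately, some members can pass by chance. The Hox cluster gene Hoxb5 was higher by 4.29 ± 0.64 (adjusted p = 0.00815), at 4.24 ± 0.81 against −0.04 ± 0.24 with TMX (SD, n = 2). Zbtb46, a transcription factor gene of classical dendritic cells, was higher by 2.40 ± 0.39 (adjusted p = 0.0112), while the other 3 Zbtb46 probe sets gave −0.32, −0.13 and 0.70. Both genes were measured below the median mean level, where noise is largest, and the level of Hoxb5 with TMX lay among the dimmest probe sets, so the size of its difference is not a measured one.

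At the level of single probe sets, limma found 0 of 45037 past the threshold after 1 h, with 2145 at an unadjusted p under 0.05 where chance alone would give 2252. The smallest adjusted p was 0.457. The 10 genes with the smallest p, which did not pass, were 8 with higher and 2 with lower values and all lay below the median mean level. They included 1700007E05Rik (4.68 ± 0.55), Wnt3 (5.22 ± 0.68), Atf2 (4.45 ± 0.57), Cxxc4 (4.10 ± 0.55) and the histone methyltransferase gene Suv39h2 (−3.96 ± 0.48). For the lists, camera's smallest adjusted p was 0.838, with 0 lists at an unadjusted p under 0.05. Leaving out 1 array gave 2 lists without HOXB4-ER without TMX 1 h replicate 2, 4 without replicate 1 of that group, and 5 without either array of HOXB4-ER with TMX 1 h, which left the 2 groups with unequal replicate numbers. The median of all probe sets lay 0.12 higher without TMX, a shift that centring each array on its median removes.

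By the test of whole gene lists, p53 target and stress genes stood higher in HOXB4-ER cells after 4 h without TMX. Growth factor signalling genes stood lower. The arrays with TMX were of 1 h, so longer culture changed together with withdrawal. With the mean of a gene's probe sets in place of the brightest, none of the lists passed (smallest camera adjusted p = 0.0514). Cells halt division and prepare for death through p53 targets such as Cdkn1a and Bbc3, and meet misfolded protein or amino acid shortage through genes such as Herpud1 and Trib3. The Sprouty and Spred genes are switched on by ERK and dampen it, so their levels follow the strength of growth factor signalling. Targets of p53 rose, with a median difference of 0.50 and 19 of 25 genes higher (camera adjusted p = 0.00281, adjusted p = 0.200 with an estimated correlation). Genes of the unfolded protein and amino acid stress response rose (median 0.27, 29 of 35 higher, adjusted p = 0.00103, and adjusted p = 0.174 with an estimated correlation), as did glycolysis and hypoxia genes (median 0.34, 27 of 32 higher, adjusted p = 0.00103, and adjusted p = 0.585 with an estimated correlation). Genes of FGF and ERK signalling with its feedback inhibitors fell (median −0.27, 25 of 40 lower, adjusted p = 0.00149, and adjusted p = 0.295 with an estimated correlation). MYC targets and ribosome biogenesis genes fell slightly (median −0.19, 29 of 39 lower, adjusted p = 0.0302, and adjusted p = 0.914 with an estimated correlation).

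Among the p53 targets, the CDK inhibitor gene Cdkn1a was higher by 2.04 ± 0.69 and Bbc3, which encodes the pro-apoptotic protein PUMA, by 1.71 ± 0.58 (log2, standard error). Trp53inp1 gave 1.22 ± 0.71 and Gadd45a 1.05 ± 0.54. After 1 h Cdkn1a had stood at 0.08 and Bbc3 at 0.24, and in HOXB4const cells at 0.09 and 0.44. Trp53inp1 had stood at −0.83 and Gadd45a at 0.44 after 1 h. In the stress list, Ddit4, an inhibitor of mTORC1, was higher by 2.23 ± 0.62, the cystine transporter gene Slc7a11 by 1.97 ± 0.61, the endoplasmic reticulum stress gene Herpud1 by 1.27 ± 0.33 and Trib3 by 1.25 ± 0.47. Trib3 already stood at 0.95 after 1 h and at 0.75 in HOXB4const cells, and Ddit4 and Slc7a11 at 0.50 and 0.47 after 1 h. In the glycolysis and hypoxia list, Ankrd37, a target of HIF1, was higher by 2.56 ± 0.43 and passed when adjusted over the list alone (adjusted p = 0.0172). The glucose transporter gene Slc2a1 gave 1.04 ± 0.42 and the oxidoreductase gene Ero1a 0.84 ± 0.36. Ddit4 and Ero1a belong to both this list and the stress list, so the calls of these lists are not fully separate. The FGF and ERK list was led by feedback inhibitors: Spry1 (−2.75 ± 0.90), Spred2 (−0.92 ± 0.31) and the RAS GTPase-activating protein gene Rasa2 (−1.32 ± 0.37), with the ERK-responsive transcription factor gene Etv5 at −0.95 ± 0.38. The MYC list was led by Tfrc (−0.80 ± 0.44), Ppan (−0.67 ± 0.45), Pprc1 (−0.63 ± 0.34) and Dkc1 (−0.44 ± 0.35). Tfrc is also a member of the erythroid list. Of the members named here, Ankrd37 alone passed adjusted over the list alone. The second, dimmer probe set of Trp53inp1 gave the other direction (−0.31 ± 1.36), as did 1 of the 5 of Spred2.

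Inflammatory, TGF-beta and erythroid lists also shifted after 4 h. Genes of the TNF and NF-kB response rose (median 0.46, 32 of 41 higher, adjusted p = 0.0302, and adjusted p = 0.914 with an estimated correlation), led by Tnip1 (1.30 ± 0.68), Birc2 (0.82 ± 0.44), Tnfrsf1b (1.38 ± 0.75) and Tnfaip2 (1.13 ± 0.62, with 1 of its 3 probe sets lower). Genes of the TGF-beta and BMP response fell (median −0.17, 22 of 32 lower, adjusted p = 0.0302, and adjusted p = 0.696 with an estimated correlation). Its member Id3, a BMP-induced inhibitor of differentiation, was lower by a difference of −4.61 ± 0.90 and passed when adjusted over the list alone (adjusted p = 0.0429), at 0.22 ± 0.56 against 4.84 ± 0.44 with TMX (SD, n = 2). Id3 lay below the median mean level and its 4 h level among the dimmest probe sets, so the size of the difference is not a measured one. Bambi gave −1.23 ± 0.33, Smad7 −1.27 ± 0.66 and Tgfbr3 −2.48 ± 1.81. Erythroid markers rose (median 0.41, 21 of 30 higher, adjusted p = 0.0108, and adjusted p = 0.415 with an estimated correlation), among them Nfe2 (1.02 ± 0.38), the water channel gene Aqp1 (2.10 ± 0.53), Epb42 (2.87 ± 0.85) and Ank1 (1.45 ± 0.64, with 3 of its 4 probe sets higher). Aqp1, Epb42 and Ank1 already stood at 2.34, 3.01 and 1.55 after 1 h, and at 1.82, −1.93 and −0.80 in HOXB4const cells. Of the 30 erythroid markers, 15 lay below the median mean level, Aqp1 and Epb42 among them, and with TMX both were so dim (1.99 ± 1.01 and −0.16 ± 0.22, SD, n = 2) that the sizes of their differences are not measured ones.

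Large single differences were measured in the inducible heat shock genes. Hspa1a went from 1.22 ± 0.35 with TMX to 7.01 ± 0.02 after 4 h (log2, SD, n = 2), and its level after 1 h was 1.12 ± 0.50. Its difference of 5.79 ± 0.64 passed when adjusted over the list alone (adjusted p = 0.00105), as did that of Hspa1b, at 4.45 ± 0.82 (adjusted p = 0.0122), which stood at −0.38 after 1 h and 1.96 in HOXB4const cells. Hspa1a lay below the median mean level and its level with TMX among the dimmest probe sets, so the size of its difference is not a measured one. The 2 genes are near-identical copies, so their probe sets can read both. The heat shock list as a group did not pass, with a median of 0.01, 12 of 24 members higher and an adjusted p of 0.232. Its median was 0.31 without the 4 h replicate 1 array and 0.20 without HOXB4-ER with TMX 1 h replicate 2, which leaves unequal replicate numbers. As deviations from the mean of all arrays, replicates 1 and 2 stood at −0.12 and 0.31 after 4 h and at −0.18 and 0.25 with TMX. Mxd1, which encodes a MAX partner that opposes MYC, was higher by 2.16 ± 0.36 (adjusted p = 0.0162), against 0.24 after 1 h and −0.65 in HOXB4const cells. Zbtb46 was also past the threshold, at 2.13 ± 0.39 (adjusted p = 0.0229), for the same dim probe set and against the same arrays with TMX as after 1 h. With Id3 and Ankrd37, these made up the 6 members past the threshold adjusted over the list alone after 4 h. Over all probe sets none of the 6 passed, and the smallest limma adjusted p among them was 0.714, for Hspa1a.

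**Figure D2:**
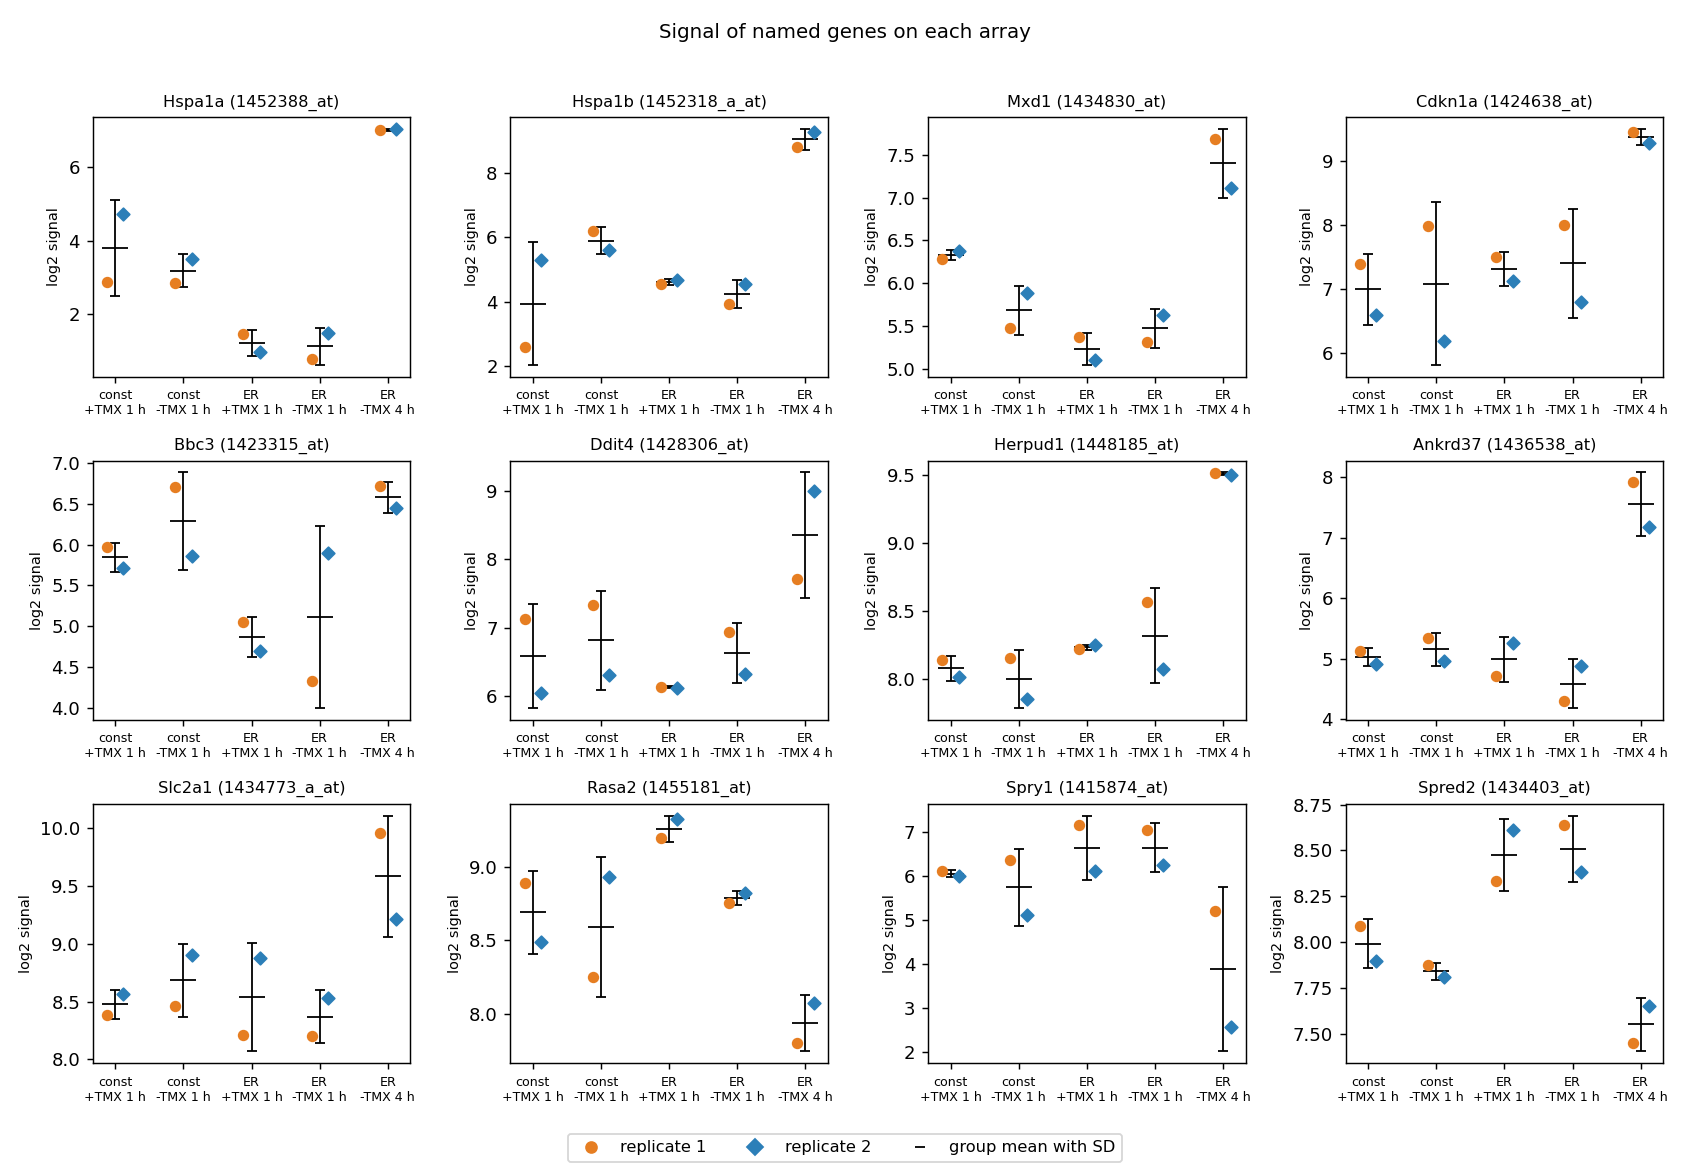
Log2 signal of 12 genes (1 probe set each) on each of the 10 arrays by group (ER, HOXB4-ER; const, HOXB4const), with circles for replicate 1, diamonds for replicate 2, and bars for the group mean and SD (n = 2). Hspa1a stands at 7.01 in the 4 h group and between 1.12 and 3.79 in the other 4 groups.

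The remaining 22 lists did not pass after 4 h, with adjusted p from 0.124 to 0.834. Hox cluster and cofactor genes had a median of −0.26, S-phase genes −0.16, granulocyte markers −0.13 and interferon response genes −0.10. Lymphoid markers stood at 0.35, mast cell and basophil markers at 0.19, polycomb and trithorax genes at 0.16, dendritic markers at 0.15, apoptosis regulators at 0.13 and G2 and M-phase genes at 0.11. G1 regulators and CDK inhibitors (0.05), megakaryocyte markers (0.05), oestrogen receptor targets (0.02), monocyte and macrophage markers (0.02), stem cell regulators (−0.01), cholesterol synthesis genes (−0.01), immediate early genes (−0.01), stromal and endothelial markers (−0.01) and Wnt pathway genes (−0.02) lay near 0, as did the Notch pathway and JAK-STAT feedback lists, at 0.08 each. Among brighter probe sets, S-phase genes (median −0.16, adjusted p = 0.0241) and Wnt pathway genes (−0.08, 0.0162) also passed as lower. For the Notch, JAK-STAT, monocyte and oestrogen receptor lists, camera's direction and the mean were down while the median was above 0. For the stem cell, stromal and cholesterol lists camera's direction and the mean were up while the median was below 0, and for the megakaryocyte list the mean alone was below 0.

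**Figure D3:**
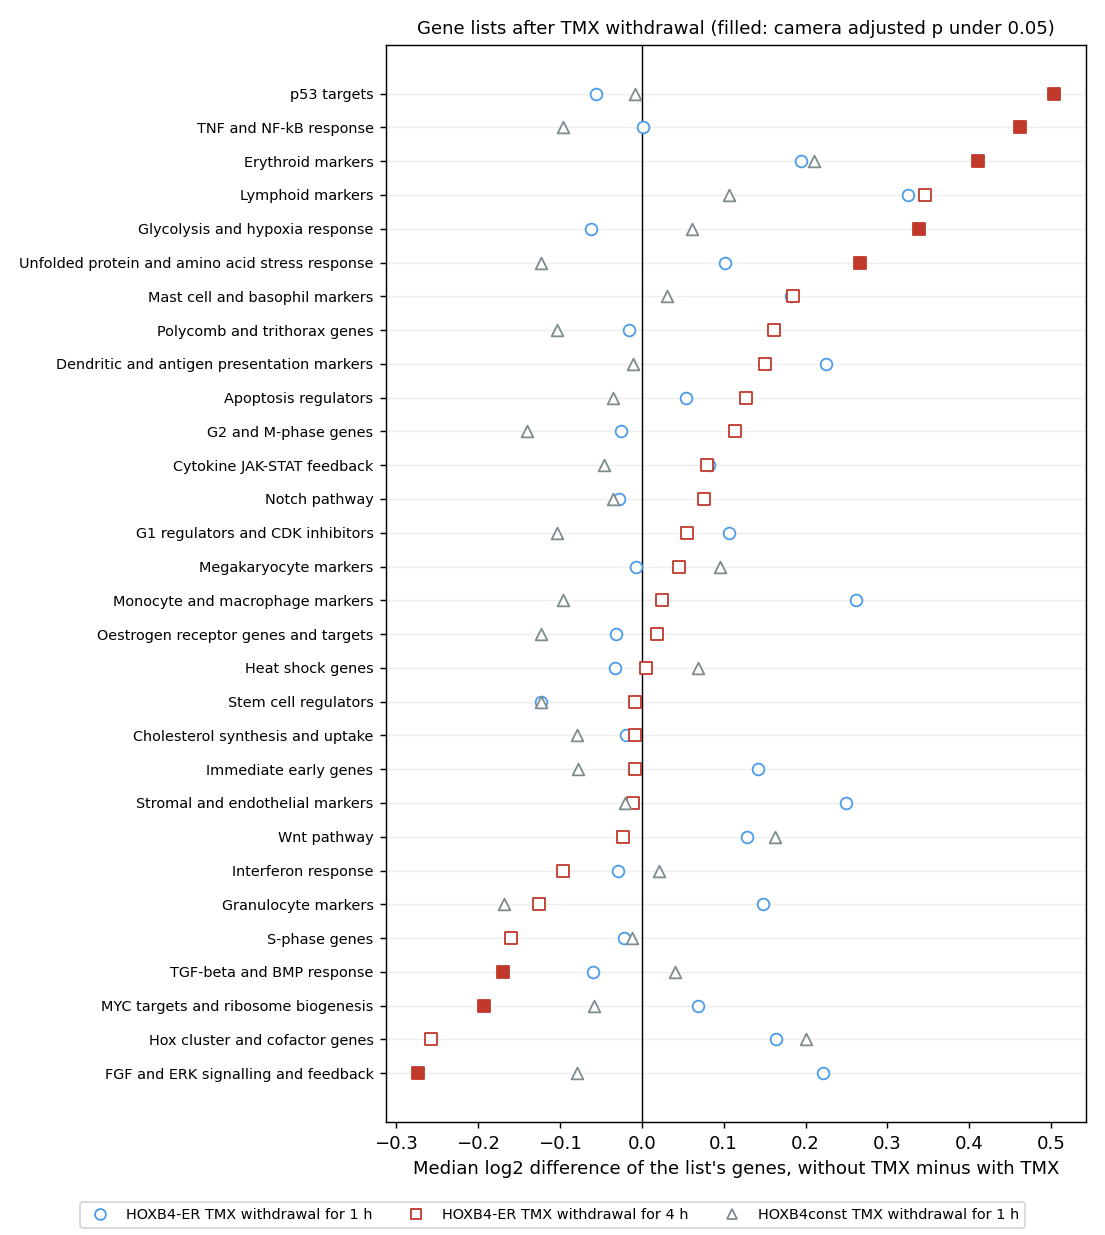
Median log2 difference of the measured genes of each of the 30 lists, without TMX minus with TMX, for HOXB4-ER at 1 h (circles), HOXB4-ER at 4 h (squares) and HOXB4const at 1 h (triangles). Filled symbols mark the 8 lists past the threshold, all of them HOXB4-ER at 4 h.

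Probe set by probe set, limma found 0 of 45037 past the threshold after 4 h, with 1509 at an unadjusted p under 0.05 and a smallest adjusted p of 0.714. Of the 10 genes with the smallest p, 5 had higher and 5 lower values and 9 lay below the median mean level: beside Hspa1a and Hspa1b (4.55 ± 0.55 for another of its probe sets) they included Stard9 (−3.32 ± 0.44), Trmt12 (−3.68 ± 0.51), Nmbr (−3.12 ± 0.49) and Peg10 (−3.32 ± 0.53). The control samples for the 4 h group had been kept with TMX for 1 h only, and the 4 h replicate 2 array had a 3′ minus 5′ difference of the Gapdh control probe sets of 3.47, against 1.39 ± 0.50 with TMX (SD, n = 2). With the mean of all probe sets of a gene in place of the brightest, 0 of the 8 lists passed (smallest adjusted p = 0.0514), with the Gapdh difference as a covariate TGF-beta did not (0.195), and with arrays centred on their medians MYC did not (0.188).

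Taking the arrays with the same replicate number together, 7 of the 8 lists had a median of the same direction in both numbers. The TNF list stood at 0.47 in replicate 1 and 0.51 in replicate 2, p53 targets at 0.42 and 0.50, the unfolded protein list at 0.32 and 0.23, glycolysis and hypoxia at 0.46 and 0.14, erythroid markers at 0.46 and 0.35, FGF and ERK at −0.39 and −0.24, and MYC targets at −0.11 and −0.24. TGF-beta genes stood at −0.21 and 0.06. Leaving out 1 array makes the compared groups unequal in replicate number. Without HOXB4-ER with TMX 1 h replicate 1, the calls for FGF and ERK (adjusted p = 0.147), TGF-beta (0.607), glycolysis and hypoxia (0.361) and erythroid markers (0.0808) ended, and without replicate 2 of that group those for p53 targets (0.0601), TNF (0.600, direction turned) and MYC (0.600, turned). Without HOXB4-ER without TMX 4 h replicate 1, TNF (0.444, turned), MYC (0.915, turned, with a median of −0.02) and erythroid markers (0.0828) did not pass, and without its replicate 2, FGF and ERK (0.0702) and TGF-beta (0.302). The unfolded protein list passed without any 1 of the 10 arrays, but with the replicate number as a block it did not pass without HOXB4-ER without TMX 4 h replicate 1 (0.109) or HOXB4-ER with TMX 1 h replicate 1 (0.0772).

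**Figure D4:**
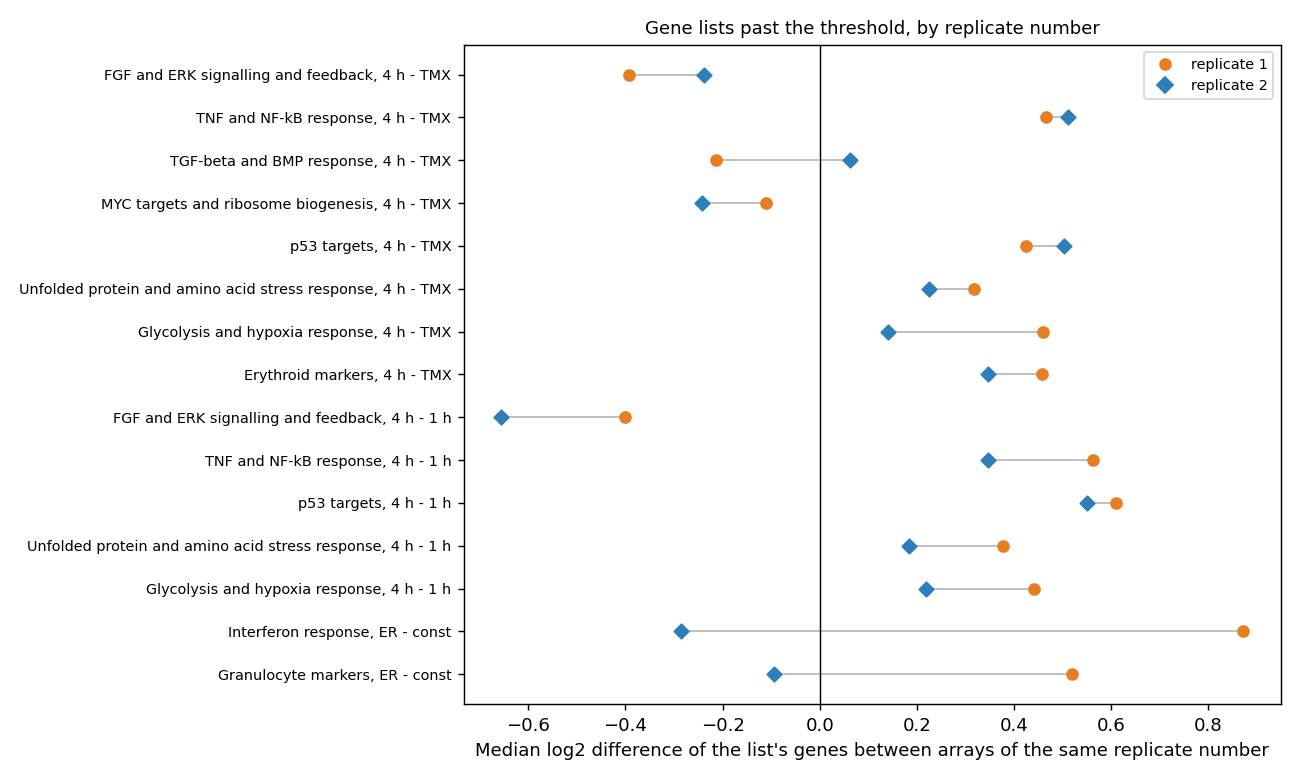
Median log2 difference of the genes of each list past the threshold, between arrays of the same replicate number (circles, replicate 1; diamonds, replicate 2), for HOXB4-ER without TMX 4 h minus with TMX, 4 h minus 1 h of withdrawal, and HOXB4-ER minus HOXB4const with TMX. All but 3 lists lie on 1 side of 0 in both numbers.

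HOXB4const cells served as the control for effects of TMX itself. None of the 30 lists shifted when TMX was removed for 1 h from cells whose HOXB4 does not need it. Median differences ran from −0.17 for granulocyte markers and −0.14 for G2 and M-phase genes to 0.20 for Hox cluster genes and 0.21 for erythroid markers, and no list member passed when adjusted over the list alone. Camera's smallest adjusted p was 0.364, with 3 lists at an unadjusted p under 0.05. With the Gapdh difference as a covariate, G2 and M-phase genes fell (median −0.30, adjusted p = 0.000362), and the list also passed without HOXB4const without TMX replicate 2 (0.00131), while immediate early and TNF genes passed as lower without HOXB4const with TMX replicate 2 (0.0126 each). For single probe sets, limma gave 0 past the threshold, 1956 at an unadjusted p under 0.05 and a smallest adjusted p of 0.854. Of the 1956, 1484 were higher and 472 lower. The median of all probe sets lay 0.09 higher without TMX, against −0.04 for the brighter ones. The replicate 1 array without TMX was the one that stood apart, with 0.0155% of its values below 0. Higher values of dim genes therefore cannot be told apart from that array's deviation. The 10 genes with the smallest p all had higher values and 9 lay below the median mean level, among them the transcription factor genes Sp6 (4.57 ± 0.60) and Six6 (3.89 ± 0.54), Plek2 (4.07 ± 0.55) and Cxxc4 (3.96 ± 0.55). Cxxc4 gave a similar difference in HOXB4-ER cells. Its mean level of 1.91 lies where noise is largest and it passed in neither construct, so no shared response can be read from it.

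The difference between the constructs in the response to 1 h of withdrawal was meant to set loss of HOXB4 activity apart from loss of TMX. Whether HOXB4-ER was inactive by then was not measured here. None of the lists differed: Hox cluster genes stood at −0.09, stem cell regulators at 0.06, FGF and ERK genes at 0.25, immediate early genes at 0.26, granulocyte markers at 0.29 and p53 targets at −0.06. Camera's smallest adjusted p was 0.950, with 0 lists at an unadjusted p under 0.05 and 0 members past the threshold adjusted over the list alone. The genes with the smallest p were Suv39h2 (−5.81 ± 0.68), the adaptor gene Nck2 (4.68 ± 0.64) and Sema6c (5.02 ± 0.71), which did not pass. Of the 10 such genes, 3 had higher and 7 lower values. Limma gave 0 probe sets past the threshold, 1698 at an unadjusted p under 0.05 and a smallest adjusted p of 0.854, with a median 95% half-width of 1.88 for the brighter probe sets. Leaving out 1 array gave 2 lists without HOXB4-ER without TMX 1 h replicate 2, and 3 and 1 without replicates 1 and 2 of HOXB4-ER with TMX 1 h.

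The 2 lengths of withdrawal were compared directly in HOXB4-ER cells, 4 h minus 1 h without TMX. As whole lists, p53 target, stress, hypoxia and inflammatory genes stood higher at the later time, and FGF and ERK signalling genes stood lower. Targets of p53 stood higher at 4 h (median 0.62, 20 of 25 higher, adjusted p = 8.43e-05, and adjusted p = 0.131 with an estimated correlation), led by Trp53inp1 (2.05 ± 0.71, with its dimmer probe set at −0.30), Cdkn1a (1.96 ± 0.69), Bbc3 (1.48 ± 0.58) and Ccng1 (1.22 ± 0.53). Glycolysis and hypoxia genes stood higher (median 0.38, 23 of 32 higher, adjusted p = 0.000605, and adjusted p = 0.731 with an estimated correlation), with Ankrd37 at 2.96 ± 0.43, Slc2a1 at 1.21 ± 0.42 and Ndrg1 at 1.17 ± 0.40. TNF and NF-kB genes stood higher (median 0.45, 33 of 41 higher, adjusted p = 0.0125, and adjusted p = 0.968 with an estimated correlation), with Nfkbie at 2.63 ± 0.90 and Tnfaip2 at 1.66 ± 0.62, and so did the unfolded protein list (median 0.22, 24 of 35 higher, adjusted p = 0.0205, and adjusted p = 0.268 with an estimated correlation), with Herpud1 at 1.19 ± 0.33 and Ddit4 at 1.72 ± 0.62. FGF and ERK genes stood lower (median −0.50, 26 of 40 lower, adjusted p = 0.0310, and adjusted p = 0.731 with an estimated correlation), with Etv4 at −2.95 ± 0.89 (a dim probe set; the other gave 0.01), Spry1 at −2.76 ± 0.90, Dusp4 at −1.26 ± 0.39 and Spred2 at −0.96 ± 0.31. Of these members, Ankrd37 alone passed adjusted over the list alone, and some other probe sets of Tnfaip2, Spred2, Ccng1 and Ndrg1 gave the other direction. All 5 lists had the same direction in both replicate numbers.

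Members past the threshold adjusted over the list alone between 4 h and 1 h were Hspa1a (5.89 ± 0.64, adjusted p = 0.000943), Hspa1b (4.83 ± 0.82, 0.00757), Ankrd37 (0.00715), Mxd1 (1.92 ± 0.36, 0.0320), Hoxb5 (−4.20 ± 0.64, 0.00920) and Id3 (−5.05 ± 0.90, 0.0254). For Hspa1a, Hoxb5 and Id3, 1 of the compared levels lay among the dimmest probe sets, so these sizes are not measured ones. Single probe sets gave 0 past limma's threshold, 2558 at an unadjusted p under 0.05 and a smallest adjusted p of 0.348, with Nck2 (−4.22 ± 0.45) and Nmbr (−4.09 ± 0.49) among the 10 smallest p. The median of all probe sets lay at −0.17, against −0.04 for the brighter ones. With the replicate number within construct as a block, 7 lists passed, adding MYC targets as lower (median −0.27, adjusted p = 0.0380) and G2 and M-phase genes as higher (0.19, 0.0380). MYC targets also passed as lower with quantile normalization (0.00333) and among brighter probe sets (0.00223). Wnt pathway genes did not pass (median −0.31, 33 of 50 lower, adjusted p = 0.177), but did with the mean of a gene's probe sets (−0.73, 0.00388). The unfolded protein list did not pass with quantile normalization (0.115), with the mean of a gene's probe sets (0.0910) or among brighter probe sets (0.0575), TNF did not among brighter probe sets (0.0717), and FGF and ERK did not with the Gapdh covariate (0.0616). Without HOXB4-ER without TMX 4 h replicate 1, TNF (0.976, turned) and the unfolded protein list (0.0745) did not pass. Without HOXB4-ER without TMX 1 h replicate 2, TNF (0.813, with a median of −0.26), the unfolded protein list (0.141) and FGF and ERK (0.141) did not pass. FGF and ERK also did not pass without the 4 h replicate 2 array (0.185), nor without any 1 of the 4 HOXB4const arrays (0.0686 for those with TMX, just over the threshold for those without). Without the 4 h replicate 2 array, or without replicate 1 of HOXB4-ER without TMX 1 h, 9 lists passed.

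With TMX present, both constructs supply active HOXB4, and this comparison shows how the 2 cell populations differed before any withdrawal. In HOXB4-ER cells interferon response genes were higher (median 0.40, 26 of 35 higher, adjusted p = 0.00190, and adjusted p = 0.928 with an estimated correlation), led by Ifitm3 (0.75 ± 0.38), Mx1 (1.71 ± 1.01), Ifit2 (1.01 ± 0.61) and Rtp4 (0.81 ± 0.52). Granulocyte markers were higher (median 0.36, 19 of 25 higher, adjusted p = 0.00240, and adjusted p = 0.928 with an estimated correlation), led by the myeloperoxidase gene Mpo (1.52 ± 0.44), Nkg7 (1.61 ± 0.64), Prtn3 (0.74 ± 0.32) and Pglyrp1 (0.76 ± 0.46). Both lists had medians above 0 in replicate 1 and below 0 in replicate 2: interferon genes stood at 0.87, with 34 of 35 higher, and at −0.29, with 10 higher, while granulocyte markers stood at 0.52, with 18 of 25 higher, and at −0.09, with 11 higher. The median of all genes was −0.01 in replicate 1 and −0.21 in replicate 2. With the replicate number within construct as a block, both lists kept camera's direction without any 1 of the 10 arrays. That block takes the difference between replicate numbers within each construct out of the spread. These fits therefore cannot test the disagreement between the 2 numbers. Zbtb46 was lower by a difference of −2.07 ± 0.39 and passed when adjusted over the list alone (adjusted p = 0.0270) but not over all probe sets (limma adjusted p = 0.762). It was read by the same dim probe set and the same HOXB4-ER arrays with TMX as after 1 h and 4 h, so these calls are not separate evidence.

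Of single probe sets, limma gave 0 past the threshold between the constructs with TMX, 1972 at an unadjusted p under 0.05 and a smallest adjusted p of 0.715. The 10 genes with the smallest p all had lower values in HOXB4-ER cells, with Limch1 (−3.91 ± 0.52) the only one above the median mean level, beside Frmd5 (−3.99 ± 0.51) and 4930552P12Rik (−3.93 ± 0.49). The median of all probe sets lay at −0.17, against −0.05 for the brighter ones. With the replicate number within construct as a block, 3 lists passed, with dendritic and antigen presentation markers added as higher (median 0.24, adjusted p = 0.00368), and among brighter probe sets FGF and ERK genes passed as higher (0.24, 0.0321), as did MYC targets with the Gapdh covariate (0.14, 0.0270). Without HOXB4-ER with TMX 1 h replicate 1, neither the interferon (adjusted p = 0.501, median −0.18) nor the granulocyte list (0.321, median −0.11) passed, and the granulocyte list did not pass without HOXB4const with TMX 1 h replicate 2 (0.393). Without replicate 2 of HOXB4-ER with TMX 1 h 8 lists passed, and without replicate 1 of HOXB4const with TMX 1 h 9 did.

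The responses after 1 h and 4 h in HOXB4-ER cells share their control arrays, which alone makes them alike. No probe set passed in both. Across probe sets, which are not independent replicates, the log2 differences had a covariance of 0.415 and a correlation of 0.388. Simulated unchanged groups that shared the same controls gave 0.538 and 0.449 on average over 100 draws, with an SD of 0.0103 for the covariance. For the brighter probe sets the covariance was 0.0589 against 0.190 in the simulation. With the replicate number as a block, the simulated covariance was 0.478, with an SD of 0.0102. The measured covariance lay well below the simulated one in each setting, so the simulation does not describe unchanged groups on these arrays. It cannot tell whether the responses are alike beyond their shared controls, and splitting the 2 control arrays would leave 1 in each part.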

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

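For the first group of lists below, the comparison with longer culture was chosen after the result was seen. A direct test of 4 h against 1 h without TMX in HOXB4-ER cells showed that 5 gene lists differed between the 2 lengths of withdrawal. The p53 targets (camera adjusted p = 8.43e-05) had a median difference of −0.06 after 1 h and 0.50 after 4 h. Glycolysis and hypoxia genes (adjusted p = 0.000605) stood at −0.06 and 0.34. The TNF and NF-kB response (adjusted p = 0.0125) stood at 0.00 and 0.46, with the reversals given above when an array is left out. The unfolded protein and amino acid stress response (adjusted p = 0.0205) stood at 0.10 and 0.27. FGF and ERK signalling genes (adjusted p = 0.0310) stood at 0.22 and −0.27. None of the 5 passed with an estimated correlation, where the adjusted p ran from 0.131 to 0.968.

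Noise of dim probe sets as the cause of the shifts at 4 h was set against the probe sets at or above the median mean level. All 8 lists past the threshold stayed past it there, with S-phase (adjusted p = 0.0241) and Wnt pathway genes (0.0162) added as lower. Members below that level ranged from 0 of 39 for MYC targets to 15 of 30 for erythroid markers, so some lists lost few or none. With the mean of all probe sets of a gene, which brings in dimmer ones, none of the lists passed (smallest adjusted p = 0.0514). Shifts made by dim probe sets would have been lost among the brighter ones, so these values argue against that noise as the cause for the 8 lists. The calls still depend on taking the brightest probe set of each gene. RNA integrity or amplified length was set against a fit with the Gapdh 3′ minus 5′ difference as a covariate, and 7 of the 8 lists stayed past the threshold. The TGF-beta list did not (adjusted p = 0.195, median −0.01 against −0.17). With that covariate monocyte (median 0.97, adjusted p = 0.00532), dendritic (1.01, 0.00326), lymphoid (0.88, 0.00642), mast cell (0.41, 0.00388) and immediate early (0.43, 0.0373) genes also passed as higher. S-phase genes passed as lower (−0.32, 0.000322). The Gapdh difference split by replicate number, so this fit cannot set RNA quality apart from the replicates, and the question stays open. Longer culture rather than loss of TMX stays open, because the 4 h arrays are compared with arrays of 1 h. Of the 8 lists, 5 also differed between 4 h and 1 h without TMX. Time and withdrawal cannot be told apart for any of the 8 lists. Loss of HOXB4 activity, the biological explanation that the design names, may therefore account for the shifts, but no HOXB4const arrays of 4 h were compared.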

How the results depend on the processing

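Settings with several choices together, the Gapdh covariate, the arrays that stood apart, the scaling of lists and leaving out an array with a block were chosen after the data were seen. Per probe set, limma's count of 0 held under each planned setting in all 6 comparisons, except that trend and robust fitting gave 1 probe set between the constructs with TMX. Brighter probe sets, trend and robust fitting with the replicate number within construct as a block gave 10 there (5 higher, 5 lower), and with the block across constructs 8 (4 and 4), 2 after 4 h (both of Hspa1b) and 1 between 4 h and 1 h (Hspa1b). The cause was not tested. Leaving out each array gave 0 probe sets throughout.

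For the lists, the estimated correlation gave 0 after 4 h, 0 between 4 h and 1 h, and 0 between the constructs. The cause was not tested. The estimated correlation was −0.012 for the unfolded protein list and 0.00496 for p53 targets, below the preset 0.01. For both lists, a correlation above the preset therefore does not account for the lost calls. The mean of a gene's probe sets gave 0 lists after 4 h. The Gapdh covariate gave 13 lists after 4 h (10 higher, 3 lower), 9 between 4 h and 1 h (7 and 2), 3 between the constructs with TMX and 1 in HOXB4const. Without both arrays that stood apart there were 4 lists after 1 h (all lower) and 9 between 4 h and 1 h (7 and 2). The cause of these was not tested. Between 4 h and 1 h the split of 4 higher and 1 lower became 3 and 2 with quantile normalization, and after 4 h that of 5 and 3 became 5 and 2 with centred arrays. Median centring removed shifts of the median of all probe sets of 0.12 after 1 h and −0.17 between 4 h and 1 h and between the constructs.

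Leaving out each array, where a lone array is assumed to vary like the other groups, gave 0 to 5 lists after 1 h, 8 to 11 after 4 h, 0 to 2 in HOXB4const, 0 to 3 for the difference of the constructs, 4 to 9 between 4 h and 1 h, and 1 to 9 between the constructs with TMX. Lists reversed by camera's direction were TNF after 4 h (adjusted p 0.444 and 0.600 reversed, range 5.00e-08 to 0.600), MYC after 4 h (0.915 and 0.600 reversed, range 1.97e-05 to 0.915) and TNF between 4 h and 1 h (0.976 reversed, range 1.35e-08 to 0.976). The median alone turned for TNF between 4 h and 1 h (−0.26) and for the interferon (−0.18) and granulocyte lists (−0.11) between the constructs. These settings leave the groups with unequal replicate numbers. With the replicate block beside each left-out array, all 15 list calls kept their direction in 10 of 10, but some stayed past the threshold in fewer: after 4 h TGF-beta in 2, MYC in 4 and erythroid markers in 7, and between 4 h and 1 h FGF and ERK in 4 and the unfolded protein list in 6. Arrays outside a comparison left its medians unchanged in these fits, so they say nothing about stability. Without HOXB4-ER without TMX 4 h replicate 1, the glycolysis and hypoxia median after 4 h was 0.11, against 0.34 with all arrays. The direction kept was camera's: the TGF-beta median after 4 h turned to 0.02 without that array.

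With the replicate block, 8 lists passed after 4 h, 7 between 4 h and 1 h and 3 between the constructs, and it changed no other call. Of 2874 recomputed differences of named probe sets, 37 changed sign. The planned floor before log2 was not run, since the values were already log2. In the simulated data the main test recovered 0% of changes of 2 in single probe sets, and brighter probe sets with trend and robust fitting 27.2%.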

Other observations

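The 2 constructs with TMX differed in a small set of single genes when brighter probe sets, a trend with robust fitting and a replicate block were combined. The general heat shock response was tested after the result for Hspa1a and Hspa1b was seen, and the genes given here were chosen after their values were seen. In that fit, with the block within construct, Cd24a, which encodes a surface glycoprotein of blood progenitors, was higher in HOXB4-ER cells for both of its probe sets past the threshold (2.50 and 2.75, limma adjusted p = 0.0167 and 0.0367). Lower in HOXB4-ER cells were the microsomal glutathione transferase gene Mgst1 (−3.64, adjusted p = 0.0167), the neuropeptide Y gene Npy (−3.37, 0.0258), Parm1 (−2.48, 0.0286), Glyat (−3.46, 0.0286) and Limch1 (−3.91, 0.0367). Another 3 probe sets, which carry no single gene symbol, were higher by 3.29, 5.93 and 3.34. With the block across constructs instead, Mgst1, Npy and 1 of the Cd24a probe sets did not pass, and Ms4a2, a chain of the high-affinity IgE receptor of mast cells, passed as lower (−1.48, adjusted p = 0.0469). With each of these settings on its own none of them passed, apart from the unnamed probe set at 3.29 with a trend and robust fitting (adjusted p = 0.0472).

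The higher Hspa1a and Hspa1b after 4 h were set against 2 explanations. A single deviating array is argued against by the 4 comparisons of a single 4 h array with a single array with TMX, of which the smallest gave a difference of 4.63 over 4 probe sets of the 2 genes. A general heat shock response of like size is argued against by the other 22 measured members of that list. Their median was −0.0330 (95% bootstrap interval −0.11 to 0.10), with 10 higher and 12 lower. A smaller one is not excluded, because the interval resamples genes and not arrays. The median of the whole list was 0.31 without the 4 h replicate 1 array, which leaves unequal replicate numbers. A response confined to the inducible HSP70 genes may remain, and handling or time in culture stays open for the same reason as for the lists.

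The interferon and granulocyte lists, higher in HOXB4-ER than in HOXB4const with TMX, were set against a single replicate pair and against RNA integrity or amplified length. The smallest of the 4 medians by list and replicate number was −0.29, for interferon genes in replicate 2, and granulocyte markers stood at −0.09 there, with 11 higher and 14 lower, which is consistent with a difference carried by 1 replicate pair. With the Gapdh difference as a covariate, 2 of the 2 lists stayed past the threshold. That difference comes from 1 control gene and split by replicate number, so this fit cannot set RNA quality apart from the replicate pair. RNA integrity or amplified length therefore stays open. The construct stays open as a biological explanation, untested apart from the population of cells that carried it.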
